A study of Pseudomonas aeruginosa PAO1 with 18 samples.

How the data were processed

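RNA was sequenced from *Pseudomonas aeruginosa* PAO1 cultures given silver nanoparticles, dissolved silver or no silver, in 18 libraries with 6 biological replicates per group, per the labels. Cells were collected on membrane filters, RNA was purified with a column kit after lysozyme and bead beating, rRNA was depleted and stranded libraries were made, per the labels' protocols. Reads were trimmed with Trimmomatic 0.38.0, aligned with Bowtie2 2.3.5.1, counted per gene with HTSeq 0.12.4 and tested with DESeq2 1.38.0, per the submitters' processing notes. The strand setting and the treatment of reads that map to several places are not given in the sources used here, so genes with near-identical copies, such as the phenazine operons, and genes with antisense neighbours are uncertain. The deposited table holds whole-number counts of reads per gene, not normalized, for 5697 features. A further total line equals the column sums (difference 0), names no gene and was left out.

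Locus tags were matched to the RefSeq gene table of assembly ASM676v1, which matched all 5697 features and supplied symbols and coding lengths. The table holds 5572 protein-coding genes, 63 tRNA, 28 ncRNA and 13 rRNA features, and 19 pseudogenes. Depth ran from 192931 to 500602 counts per library. Counts were kept as deposited, low-count genes were removed with filterByExpr (4725 genes kept) and libraries were scaled by TMM (factors 0.705 to 1.23). The quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was fitted over all 18 libraries with group and library series, the prefix 34 or 38 of the library name, as terms. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 3 comparisons were AgNP against control, Ag(aq) against control and AgNP against Ag(aq). Differences between library series were tested by the interaction of group and series. CPM were computed from the TMM-scaled library sizes of the genes kept. The SE of a log2 fold change was its size divided by the square root of the F statistic. Every adjusted p of a single gene comes from edgeR.

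The 31 gene lists, the comparisons, the tests, the gene-naming rule and most alternatives were chosen before the data were examined. The lists have 650 entries, of which 647 are in the table and 544 were tested, with no gene in more than 1 list. The entries PA3574.1, PA0632 and PA0642 matched no feature by name and were not analysed here as list members. PA3574a, the feature after PA3574 in the table, was looked at outside the lists. List tests used camera of limma 3.58.1 with the correlation between genes estimated per list and adjustment over the 31 lists of a comparison. A preset correlation of 0.01 and the fry test were alternatives. Unless stated otherwise, the adjusted p of a list is from the deposited counts with TMM scaling, also beside counts from other settings. Calls of members were also adjusted over the list alone. The text names, per comparison, the 6 largest rises and 6 largest falls among called genes with a mean CPM of at least 10 and the same sign in both series. It also names the 2 called members with the largest change in the 8 lists with most calls, and always 10 genes of metal, peroxide, chaperone, envelope and DNA damage responses. The rule named 35, 36 and 32 genes, and other genes are examples chosen after their values were seen.

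The step was tested on simulated data with the mean levels and sizes of all 18 libraries (4552 genes). Each gene had the same spread in every group, and AgNP and control had no series effect, unlike in the data. For AgNP against control it recovered 58 of 95 genes changed 2-fold and 94 of 94 changed 4-fold, with 7 false calls (4.40%). Of 97 genes given a 4-fold difference between series under Ag(aq), 38 were recovered. The uniform read floor of a library was set at the 5th percentile of read density among genes of at least 600 bp. The correlation of both responses was compared with 20 simulations of unchanged groups against the same controls, whose 0 to 2 calls were too few to compare overlaps. Overlap was compared with n1 × n2 / N and with 18 splits of the controls. Up to 100 of 462 splits of the 12 libraries per comparison were refitted, the real one included. List members were also compared, after the results were seen, with the 20 other protein-coding genes nearest in length, or in length and mean level. Group differences of library measures were tested by two-sided exact permutation of all libraries of both groups, without regard to library series.

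Alternatives were other size factors, no or a stricter count filter (at least 50 counts in 6 libraries), no series term, the 12 libraries compared alone, each series alone, a replicate block, no rRNA and tRNA, DESeq2 1.42.0, and leaving out each library. Alternatives added after the data were seen were total counts only, subtraction of the read floor, AgNP libraries summed per series (because they differed by little more than counting error), and leaving out control replicates 1 and 5 together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.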

Results

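The 18 libraries measured mRNA in *Pseudomonas aeruginosa* PAO1, a model strain of an opportunistic pathogen that also lives in soil and water. Cultures received silver nanoparticles (AgNP), dissolved silver (Ag(aq)) or no silver, with 6 biological replicates per group. The question was how the cells responded to each form of silver at sublethal exposure, and whether the particle form and the dissolved form gave different transcript profiles. Doses and exposure times are not in the labels. Silver binds thiols and enters the handling routes of monovalent copper, so genes of copper export, sulfur metabolism, oxidative defence and protein quality control were among the 31 gene lists fixed in advance.

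Each library carried between 192931 and 500602 counts over 5697 features (mean 314952 ± 82913, SD, n = 18), which is shallow for a bacterial transcriptome. The mean depth was lowest in AgNP (261224), against 339362 in Ag(aq). The median count per gene lay between 13 and 28, and in simulations of AgNP against control at these depths 61.1% of 2-fold changes and all 94 of the 4-fold changes were recovered. Those simulations had equal spread in both groups and no series effect, so recovery in the data may differ. Features of rRNA took 0.568% of counts on average. Library names carry a prefix, 34 for replicates 1 to 3 and 38 for replicates 4 to 6 of every group, whose meaning is not stated. It is called the library series and was a covariate unless stated otherwise. Intervals from read counts cover counting error only.

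The first principal component of log2 CPM held 48.4% of the variance and the second 19.6%. The uniform read floor, the share of counts that an even spread of reads over the chromosome could hold, was 16.5% ± 2.41 (SD, n = 6) in AgNP, 5.15% ± 3.29 in the controls and 9.95% ± 4.45 in Ag(aq). The difference between AgNP and control gave a two-sided exact permutation p of 0.00216 (adjusted over 15 such tests 0.0108). That test took the libraries as independent and did not keep to library series. Counts of weakly expressed genes under AgNP are therefore also given after that floor was subtracted.

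**Figure D1:**
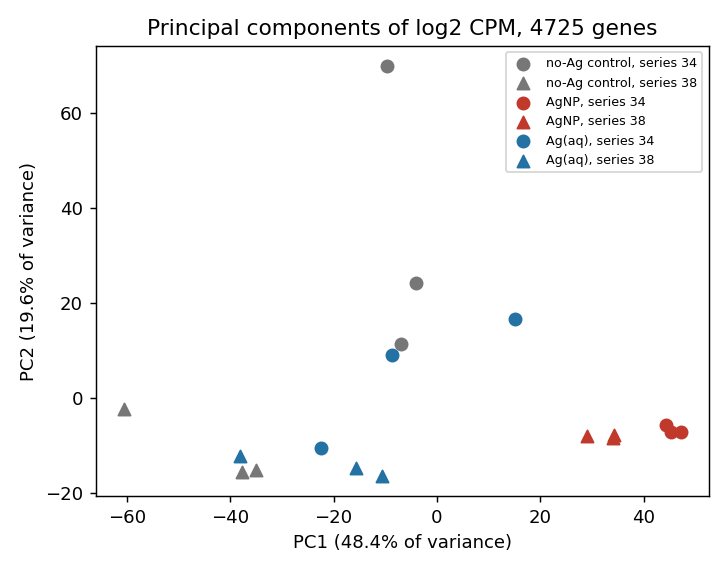
First (48.4% of variance) against second (19.6%) principal component of log2 CPM for the 18 libraries, coloured by treatment, with circles for library series 34 and triangles for series 38. The AgNP libraries lie apart from the control and Ag(aq) libraries.

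Silver nanoparticles changed the transcript levels of a large share of the genes tested. Transcripts rose for the export of copper-like metals, the capture of sulfur from sulfate and organic sulfur compounds, and the enzymes that remove peroxides. Most single genes of ribosomal proteins, protein export and ATP synthase fell, although none of those lists passed the list test. Of 4725 genes tested with edgeR, 2833 changed (60.0%), of which 1411 rose and 1422 fell. Among these, 848 rose and 760 fell at least 2-fold. After the read floor was subtracted 2008 genes were called. AgNP replicates of a series differed by little more than counting error (chi-square per degree of freedom 1.05 to 1.50, controls 2.26 to 15.0), and with AgNP libraries summed per series for that reason 1751 were called. Scaled by total counts alone, 73.2% of the called genes rose, against 49.8% with composition factors, and the median gene then shifted by 0.42 on the log2 scale, so directions are relative to the median gene.

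Genes for the use of organic sulfur were among the largest rises. PA3444, an alkanesulfonate monooxygenase gene, rose by a log2 fold change of 6.32 ± 0.34 (SE, adjusted p = 2.06e-12). Its CPM was 20.5 ± 15.1 (SD, n = 6) in the controls and 1655 ± 65.0 under AgNP. The neighbouring sulfonate-binding protein gene PA3445 rose by 5.75 ± 0.27 (adjusted p = 7.44e-13), and the taurine transport gene PA3938 by 4.45. Of 14 organosulfur genes tested, 13 rose and 1 was not called, with the same 13 adjusted over the list alone (median 3.77, adjusted p = 3.00e-04 with an estimated correlation). Sulfate uptake and cysteine synthesis followed, with 7 of 12 genes risen, 1 fallen and 4 not called, the same counts adjusted over the list alone (median 0.95, adjusted p = 0.0125). That list did not pass without the series term, within either series or with total counts. There the sulfate-binding protein gene sbp rose by 4.02 and the transporter gene cysA by 3.16, while the cysteine synthase gene cysM fell by 1.31.

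Metal export genes rose strongly. The gene of the copper-exporting ATPase, PA3920, went from 232 ± 113 CPM to 14349 ± 925 CPM, a log2 fold change of 6.00 ± 0.30 (adjusted p = 8.86e-13). The copper-inducible periplasmic protein gene ptrA (PA2808) rose by 5.13 ± 0.37 (adjusted p = 1.88e-10), or 6.00 without control replicate 5. PA3523, the adaptor of a copper-responsive efflux pump, rose by 4.67 ± 0.29. Of 12 copper and silver export genes, 9 rose and 3 were not called, the same adjusted over the list alone (median 3.55, adjusted p = 0.0111). The list did not pass within series 38. That median was 4.68 without control replicate 5, 4.98 in series 34 and 2.51 in series 38, and 4 members differed between series. PA3518, in a gene cluster beside that list, rose by 5.43 ± 0.30 (adjusted p = 2.57e-12). All 8 zinc and cadmium efflux genes rose, over all genes and adjusted over the list alone (median 2.44, adjusted p = 0.0439). That list call was lost in 9 of the 18 fits that each left out 1 library, where its adjusted p ran from 0.0279 to 0.104 and its median from 2.22 to 2.69. They included the ATPase gene PA3690 (3.65) and the efflux pump gene czcA (1.68 ± 0.22, adjusted p = 2.57e-06).

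Genes for defence against peroxides rose with them. Catalase katB (PA4613) increased by 4.54 ± 0.26 (adjusted p = 3.61e-12) and the alkyl hydroperoxide reductase subunit ahpF (PA0140) by 3.83 ± 0.19 (adjusted p = 8.86e-13). The CPM of ahpF was 215 ± 34.9 in the controls and 3052 ± 132 under AgNP. PA3287, which codes for an ankyrin-repeat protein, rose by 5.27 ± 0.27. Of 19 oxidative stress genes, 13 rose, 2 fell and 4 were not called, equally adjusted over the list alone (median 1.86, adjusted p = 0.00143). The iron superoxide dismutase gene sodB fell by 1.67. Among 17 heat-shock genes 10 rose and 3 fell (11 and 3 adjusted over the list alone), with an adjusted p = 0.594 with an estimated correlation. Their median was 0.38 in series 34 and 1.85 in series 38, with 9 of 17 called different. The small chaperone gene ibpA rose by 4.66 and the chaperone gene dnaK by 1.90 ± 0.44 (adjusted p = 0.00115), whereas the chaperonin gene groEL (0.91 ± 0.40, adjusted p = 0.0521) was not called, but was in 6 of the 18 fits without 1 library (0.69 to 1.10). The DNA repair gene recA (-0.23 ± 0.20, adjusted p = 0.318) was not called either.

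**Figure D2:**
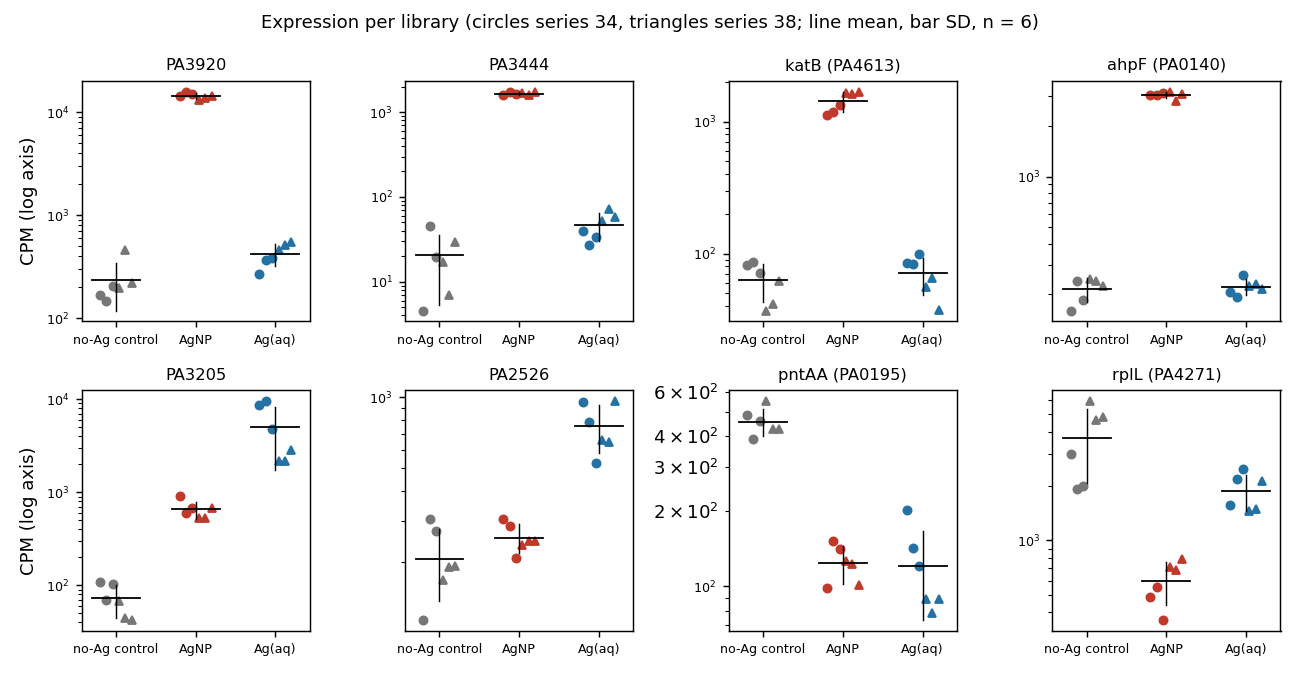
CPM on a log axis for 8 genes (PA3920, PA3444, katB, ahpF, PA3205, PA2526, pntAA and rplL) in each library of the control, AgNP and Ag(aq) groups, with the group mean as a line and the SD as a bar (n = 6). PA3444, katB and ahpF are high in AgNP alone of the 3 groups, PA2526 in Ag(aq), and pntAA is low under both forms of silver.

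Many genes of growth and energy metabolism fell, in lists that did not pass the list test. Beside counts from total-count scaling or floor subtraction, a list's adjusted p is still that of the deposited counts with TMM scaling. All 51 ribosomal protein genes tested fell, also adjusted over the list alone, with a median of -1.90 (adjusted p = 0.380 with an estimated correlation), and 48 fell with total counts. The median was -1.24 in series 34 and -2.39 in series 38, with 5 members called different. The largest falls there were rpmF (-2.60 ± 0.50) and rplL (-2.58 ± 0.27, adjusted p = 1.24e-07). Longer genes had higher counts more clearly in AgNP (Spearman 0.539) than in the controls (0.325, exact permutation p = 0.00216, adjusted 0.0108), and ribosomal genes are short and abundant. Beside their median of -1.90, other genes nearest in length had -0.32, and those nearest in length and mean level -0.82, a comparison chosen after the result was seen. Of 20 genes of outer membrane assembly and protein export, 19 fell (adjusted p = 0.340), as adjusted over the list alone, and 16 with total counts. Among them were the translocon genes secY (-2.31 ± 0.30) and secE (-1.81 ± 0.40). ATP synthase lost transcripts in 9 of 9 genes (median -1.71, adjusted p = 0.476), and in 7 with total counts. That median was -0.52 in series 34 and -2.58 in series 38, with 5 of 9 members called different. For the NADH dehydrogenases, 12 of 18 genes fell (adjusted p = 0.476), or 5 with total counts. Iron-sulfur cluster assembly showed 6 of 8 genes fallen (adjusted p = 0.557), or 2 with total counts. These counts did not differ when adjusted over the list alone. Across 4684 protein-coding genes, the change under AgNP was lower at higher mean level (Spearman -0.49). List medians and those of genes nearest in length and mean level were -1.71 and -1.10 for ATP synthase, and -1.37 and -0.76 for export. They were -0.74 and -0.46 for the NADH dehydrogenases, and -0.96 and -0.85 for iron-sulfur cluster assembly.

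The terminal oxidase list had 2 genes risen and 5 fallen of 16, and the TCA cycle list 2 and 7 of 15, each unchanged when adjusted over the list alone (adjusted p = 0.813 and 0.673). Succinate dehydrogenase sdhC fell by 1.83 and isocitrate lyase aceA rose by 1.27, and the median of the TCA genes was -0.24 but 0.19 with total counts. Of 11 thiol and disulfide genes 6 fell, with or without adjustment over the list alone, among them thioredoxin trxA (-1.53) (adjusted p = 0.558). With total counts, 2 rose and 4 fell. The median of the 11 genes was -0.45, against -0.80 for genes nearest in length and mean level. Besides pilA, the largest single falls were in the water channel gene aqpZ (-3.10 ± 0.32, adjusted p = 1.17e-07), the cold-shock gene PA0456 (-3.01 ± 0.27, adjusted p = 1.01e-08), methionine synthase metE (-2.97 ± 0.44, adjusted p = 1.43e-05) and PA0046 of unknown function (-2.90 ± 0.30). PA5348, a gene of a DNA-binding protein, fell by 2.90 ± 0.54, or by 2.18 without control replicate 1.

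Genes of surface structures fell in part, and none of their lists passed the list test. Of 18 type IV pilus genes 12 fell (14 adjusted over the list alone, 9 with total counts, adjusted p = 0.340), led by the pilin gene pilA (-2.91 ± 0.41, adjusted p = 7.08e-06). The flagellum and chemotaxis list had 14 genes fallen and 1 risen of 32 (13 and 1 adjusted over the list alone, adjusted p = 0.557), but 5 fallen and 4 risen with total counts. Its chemotaxis genes cheZ (-1.42 ± 0.23) and cheY (-1.41 ± 0.29) had the largest falls. Type VI secretion (median -0.81 in series 34 and 0.12 in series 38) had 6 of 17 genes fallen (5 adjusted over the list alone, adjusted p = 0.673), and 1 fallen and 1 risen with total counts. In the pyocin list 13 genes fell and 2 rose of 33 (adjusted p = 0.557), the same adjusted over the list alone, but 3 fell and 5 rose with total counts. Its phage tail-like genes PA0615 (-1.45 ± 0.21) and PA0616 (-1.10 ± 0.25) fell. The envelope stress sigma factor gene algU fell by 1.04 ± 0.23 (adjusted p = 9.11e-04). Its list split into 3 risen and 4 fallen of 14 (adjusted p = 0.870), equally adjusted over the list alone, or 4 and 1 with total counts. List medians and those of genes nearest in length and mean level were -0.78 and -0.40 for type IV pili (17 protein-coding genes), and -0.37 and -0.29 for the flagellum. They were -0.40 and -0.20 for type VI secretion, and -0.40 and -0.42 for pyocins.

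Envelope and nutrient genes of several regulons rose without passing the list test. The PhoPQ and PmrAB list had 11 of 16 genes risen and 1 fallen (12 and 1 adjusted over the list alone, adjusted p = 0.476 with an estimated correlation), with the outer membrane gene oprH at 2.81 ± 0.37 (adjusted p = 3.90e-06). Among RND multidrug efflux genes 12 of 31 rose and 1 fell (12 risen adjusted over the list alone, adjusted p = 0.380). Siderophore genes rose in 11 of 17 for pyoverdine with 1 fallen (12 and 1 adjusted over the list alone, adjusted p = 0.594). The pyoverdine median was 1.82 in series 34 and 0.04 in series 38. Pyochelin rose in 7 of 8 genes (adjusted p = 0.380) and heme and ferrous iron uptake in 4 of 8 (adjusted p = 0.340), each the same adjusted over the list alone. The TonB-linked gene exbB1 rose by 2.84 and the siderophore synthesis gene pvdL by 1.68. For SOS and DNA repair, 1 of 10 genes rose, by either adjustment (adjusted p = 0.813).

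Several lists of weakly expressed genes held many rises, and fewer of their members could be tested after the read floor was subtracted. Genes were filtered anew after subtraction, and a member could stay by being high in the 6 AgNP libraries alone. The share risen among members that stayed therefore cannot decide on background. With the same genes tested, 46.4% of the rises among the 1182 genes of lowest read density stayed called. Denitrification rose in 19 of 22 genes (adjusted p = 0.380), including nirJ (1.66 ± 0.44) and nitrous oxide reductase nosZ (1.50 ± 0.33), and in 14 of 16 after subtraction. Phosphate starvation genes rose in 9 of 13 (12 adjusted over the list alone, adjusted p = 0.423) and in 6 of 8 after subtraction. Type III secretion rose in 7 of 11 genes (adjusted p = 0.423) and in 2 of 3 after subtraction. Zinc starvation genes rose in 7 of 13 (adjusted p = 0.476) and in 3 of 9 after subtraction. Quorum sensing genes had 12 risen and 2 fallen of 22 (adjusted p = 0.476), and 3 and 1 of 8 after subtraction. There the cyanide synthesis gene hcnC rose by 1.69 ± 0.42 and the phenazine gene phzE1, which shares reads with a near-identical copy, by 1.65 ± 0.36. The biofilm list had 14 genes risen and 11 fallen of 29 (adjusted p = 0.870), but 3 and 10 of 18 after subtraction. Alginate genes algL (1.89 ± 0.35) and algE (1.75 ± 0.32) rose while the Psl gene pslA fell by 1.53. Except for phosphate, the deposited counts gave the same numbers adjusted over the list alone. Several of these lists rose little or no more than other genes nearest in length and mean level. List and matched medians were 1.07 and 0.92 for denitrification, 0.68 and 0.53 for phosphate starvation, and 0.88 and 0.77 for zinc starvation. They were 0.90 and 0.89 for quorum sensing, 0.85 and 1.00 for type III secretion, and 0.52 and 0.85 for the biofilm list.

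Past the list test with an estimated correlation were 5 of the 31 lists under AgNP, against 22 with a preset correlation of 0.01 and 25 with the fry test. Of the 1182 genes with the lowest read density, 812 rose and 15 fell, and their calls depend most on the read floor.

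**Figure D3:**
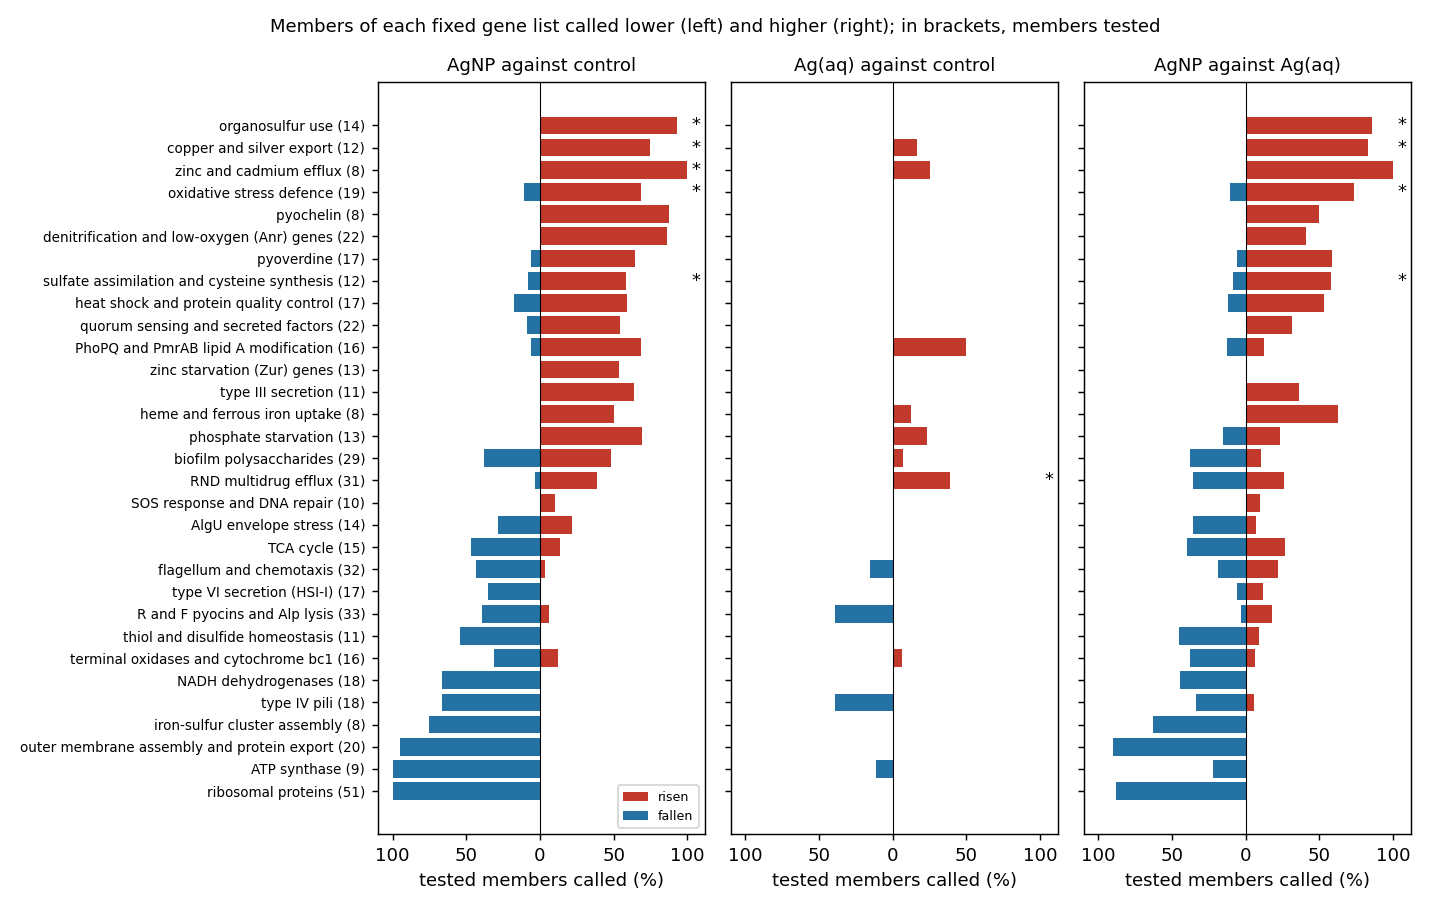
Share (%) of tested members called higher or lower for each of the 31 gene lists in each of the 3 comparisons, with a star where the list test with an estimated correlation passed. Under AgNP the star marks copper export, zinc and cadmium efflux, organosulfur use, sulfate assimilation and oxidative stress, and under Ag(aq) RND efflux alone.

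Dissolved silver changed far fewer genes. It raised multidrug efflux genes, the only list to pass the list test, though not in every setting, and an envelope stress cluster. Single lipid A modification genes rose and single pyocin and pilus genes fell. No oxidative stress gene was called by edgeR (2 of 19 by DESeq2, and 1 risen and 1 fallen adjusted over the list alone), and the organosulfur list passed only with a preset correlation (adjusted p = 0.00132) and with fry (0.00674). Of 4725 genes tested, 233 changed (4.93%), with 105 risen and 128 fallen, of which 77 and 55 at least 2-fold. That fit shares its estimate of spread with the AgNP libraries, whose replicates within a series varied least. With only the 12 libraries compared 114 genes were called, and with AgNP libraries summed per series 111. With total counts alone 79.9% of the calls were rises, against 45.1%, and the median gene shifted by 0.21.

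An envelope stress cluster gave the largest rises. PA3205, a periplasmic protein gene beside the sensor kinase gene PA3206, rose by 5.96 ± 0.32 (adjusted p = 1.80e-11), from 73.2 ± 28.4 to 5003 ± 3275 CPM. PA3206 rose by 4.18 ± 0.41 (adjusted p = 1.40e-06) and PA3207 by 3.51 ± 0.46 (adjusted p = 4.69e-05). PA2506, of unknown function, rose by 3.65 ± 0.46, PA3575, of unknown function, by 2.97 ± 0.32 (adjusted p = 4.26e-06), and dsbG, for a periplasmic disulfide isomerase, by 2.71 ± 0.34 (adjusted p = 2.87e-05). Between library series 34 and 38, PA2506 (1.03 and 5.07), PA3206 (5.47 and 2.89) and dsbG (1.48 and 3.39) differed.

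Of 31 RND efflux genes 12 rose and 19 were not called (15 risen adjusted over the list alone), and this list alone passed the test (median 0.56, adjusted p = 0.0123). It did not pass within either series, with total counts or with AgNP libraries summed. PA2527 (1.96 ± 0.26, adjusted p = 5.20e-05) and PA2526 (1.87 ± 0.22, adjusted p = 1.61e-05) belong to 1 operon for a multidrug pump, and PA2018 of the aminoglycoside pump rose by 1.43. In the PhoPQ and PmrAB list 8 of 16 genes rose (15 adjusted over the list alone, adjusted p = 0.198 with an estimated correlation), with oprH at 1.87 ± 0.37 and the regulator phoP at 1.65 ± 0.37. Phosphate uptake genes rose in 3 of 13 cases (5 adjusted over the list alone, adjusted p = 0.101), with pstS at 1.44 ± 0.27 and pstA at 1.38 ± 0.24. Zinc and cadmium efflux had 2 of 8 risen (5 adjusted over the list alone, adjusted p = 0.305), among them czcC (1.29), while czcA (0.61 ± 0.22, adjusted p = 0.126) was not called.

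Copper and silver export did not pass as a list. PA3920 rose by 0.87 ± 0.25 (adjusted p = 0.0463) and PA3519 by 1.09 ± 0.30 (adjusted p = 0.0388), 2 of 12 genes (3 adjusted over the list alone, adjusted p = 0.590 with an estimated correlation, median 0.22, mean -0.01). The PA3920 call was lost in 13 of the 18 fits without 1 library (0.80 to 1.14) and that of PA3519 in 8 (0.89 to 1.52). PA3523 (0.65 ± 0.32, adjusted p = 0.264), katB (0.18 ± 0.25, adjusted p = 0.736) and ahpF (0.04 ± 0.18, adjusted p = 0.926) were not called. Alginate genes algE (1.28 ± 0.33) and algA (0.96 ± 0.27) rose, 2 of 29 biofilm genes by either adjustment (adjusted p = 0.527), with calls lost in 3 and 9 of those fits (1.14 to 1.45 and 0.74 to 1.12). The ferrous iron transporter gene PA4358 rose by 1.03, 1 of 8 in its list by either adjustment (adjusted p = 0.940, upwards, against a median of -0.16), as did the oxidase gene ccoN2 (0.88), 1 of 16 (adjusted p = 0.940).

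Pyocin genes fell in 13 of 33 cases (25 adjusted over the list alone, 4 with total counts, adjusted p = 0.0888), with PA0619 (-1.09 ± 0.23) and PA0646 (-1.02 ± 0.24) lowest among the called ones. Type IV pilus genes fell in 7 of 18 (13 adjusted over the list alone, 1 with total counts, adjusted p = 0.101), with pilA at -1.48 ± 0.38 and pilN at -1.16 ± 0.29. Flagellar genes fell in 5 of 32 (13 adjusted over the list alone, adjusted p = 0.203), a call none of them kept with total counts (median -0.23), with flgD at -0.83 ± 0.23 and flgI at -0.76 ± 0.19. Without control replicate 1 these 4 pilus and flagellar genes were not called (-0.89, -0.98, -0.60 and -0.61), and the calls were lost in 4, 4, 12 and 5 of the 18 fits. ATP synthase had atpC fallen (-0.89), 1 of 9 or 7 adjusted over the list alone (adjusted p = 0.385).

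Among single genes, the porin gene oprD fell by 2.21 ± 0.35 (adjusted p = 4.67e-04), as did the ethanol oxidation genes exaB (-2.76 ± 0.64) and exaC (-2.23 ± 0.45). Without control replicate 1 these changes were -1.56, -1.53 and -1.43. The transhydrogenase gene pntAA fell by 1.95 ± 0.20 (adjusted p = 2.03e-06), from 456 ± 56.4 to 120.4 ± 47.0 CPM, as did metE (-2.59 ± 0.43). The arsenic repressor gene arsR had 1 read in Ag(aq) and 21 in the controls, a ratio of 24.9 with a 95% exact counting interval from 4.01 to 1031. Its fitted change was -3.81 ± 0.65 (adjusted p = 0.00102), or -4.95 without Ag(aq) replicate 3. The genes dnaK (-0.13, adjusted p = 0.908), groEL (0.28, adjusted p = 0.764), algU (0.05, adjusted p = 0.921) and recA (-0.17, adjusted p = 0.691) were not called. For dnaK and groEL this averages opposite changes called in each library series in the joint fit, -1.79 and 1.62 for dnaK and -1.28 and 1.81 for groEL in series 34 and 38. In a fit of series 34 alone groEL (PA4385) was not called (-1.32, adjusted p = 0.126).

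No member was called by edgeR in 19 of the 31 lists, which hold 319 tested genes, of which 43 had an unadjusted p under 0.05 and 9 were called by DESeq2. They include oxidative stress (median -0.12, adjusted p = 0.940) and sulfate assimilation (median 0.08, adjusted p = 0.934), and for organosulfur use 1 of 14 was called adjusted over the list alone (median 0.57, adjusted p = 0.203). The 233 calls fell to 143 without Ag(aq) replicate 4, 150 without Ag(aq) replicate 5 and 150 without control replicate 4, and 2 or 3 lists passed without control replicates 3 or 1.

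The direct comparison of both silver forms tested where the AgNP and Ag(aq) cultures differed. Since doses and exposure times are not in the labels, it cannot separate the form of silver from its amount or the time. Transcripts for sulfur capture, copper export and peroxide defence were higher under nanoparticles. The efflux operon raised by dissolved silver was lower, as were many ribosomal and export genes, whose lists did not pass. Of 4725 genes 2017 differed (42.7%), 923 higher and 1094 lower in AgNP, and 357 and 565 at least 2-fold. With AgNP libraries summed per series 692 differed, 387 higher and 305 lower. With total counts alone 59.1% were higher, against 45.8%, and the median gene shifted by 0.26, against 0.07.

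In AgNP the organosulfur list was higher in 12 of 14 genes (adjusted p = 1.09e-04), with PA3445 at 5.16 ± 0.26 (adjusted p = 1.99e-12) and PA3444 at 5.15 ± 0.31. Oxidative stress genes were higher in 14 and lower in 2 of 19 (adjusted p = 2.78e-04), with katB at 4.36 ± 0.25, PA3287 at 4.22 ± 0.24 and ahpF at 3.79 ± 0.19. Sulfate assimilation was higher in 7 and lower in 1 of 12 (adjusted p = 0.00590). Copper export was higher in 10 of 12 (adjusted p = 0.00868), with PA3920 at 5.13 ± 0.29 (adjusted p = 5.87e-12), PA2807 at 5.04 ± 0.70, ptrA at 4.64 ± 0.34 and PA3523 at 4.02 ± 0.27. These 4 lists gave the same counts adjusted over the list alone, but sulfate assimilation did not pass without the series term or within either series, nor copper export within series 38. All 8 zinc and cadmium efflux genes were higher by either adjustment (adjusted p = 0.0635 with an estimated correlation), with czcA at 1.07 ± 0.20. The arsenic repressor gene arsR differed by 6.01 ± 0.48 (7.13 without Ag(aq) replicate 3), with 102 reads in AgNP and 1 in Ag(aq).

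Heat-shock genes were higher in 9 and lower in 2 of 17 (9 and 3 adjusted over the list alone, adjusted p = 0.762 with an estimated correlation). Disaggregase clpB (2.71 ± 0.30), ibpA (3.83 ± 0.42) and dnaK (2.03 ± 0.44, adjusted p = 9.59e-04) were higher, while groEL (0.64 ± 0.40, adjusted p = 0.191) and recA (-0.06 ± 0.20, adjusted p = 0.805) did not differ detectably. Ribosomal protein genes were lower in 45 of 51 (46 adjusted over the list alone, 40 with total counts, adjusted p = 0.714), with rpsU at -2.68 ± 0.42 and rpmH at -2.54 ± 0.54. Export and outer membrane assembly was lower in 18 of 20 by either adjustment (adjusted p = 0.298), and in 17 with total counts, with PA3822 (84.2 ± 23.9 CPM in AgNP and 339.9 ± 145 in Ag(aq)) and PA4461 at -1.78 ± 0.21. Translation initiation factor infA (-2.56 ± 0.43), aqpZ (-3.32 ± 0.32, adjusted p = 5.47e-08), its neighbour PA4033 (-3.04 ± 0.43) and algU (-1.10 ± 0.23) were lower.

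The RND list split, with 8 genes higher and 11 lower in AgNP of 31 (9 and 12 adjusted over the list alone, adjusted p = 0.810). PA1435, a pump gene, was higher by 1.83 ± 0.30, and PA2525 of the operon raised by dissolved silver was lower (-1.77 ± 0.21, adjusted p = 1.23e-06). PA3205 was also lower (-2.73 ± 0.28, adjusted p = 9.16e-08). Psl genes pslA (-1.51 ± 0.22) and pslL (-1.32 ± 0.21) were lower, within a biofilm list of 3 higher and 11 lower of 29 (5 and 11 adjusted over the list alone, adjusted p = 0.816). Flagellar genes went both ways by either adjustment, 7 higher and 6 lower of 32 (adjusted p = 0.983), or 8 and 3 with total counts, with flgE at 0.90 ± 0.22 and motor gene motA lower (114 ± 16.1 CPM in AgNP and 231 ± 73.8 in Ag(aq)). The outer membrane gene oprH was higher by 0.94 ± 0.36 (adjusted p = 0.0415), a call lost in 8 of the 18 fits without 1 library (0.66 to 1.10). Zinc starvation was the only list of the 31 with no edgeR call, where 2 of 13 genes had an unadjusted p under 0.05 and 2 were called by DESeq2.

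Both responses against control shared 161 genes in the same direction and 4 in opposite directions. Of these, 69 rose and 92 fell in both, against 31.4 and 38.5 for independent lists, and they made up 69.1% of the Ag(aq) calls. Members include PA3205, pntAA and metE. With the controls split between the contrasts the overlap averaged 74.3 over 18 splits (26 to 196). Across genes, which are not independent, the log2 fold changes had r = 0.552 and a covariance of 0.295, against 0.506 and 0.0454 simulated without effects and 0.389 and 0.236 with split controls. The covariance exceeded the simulated one by 0.249. Of the 233 Ag(aq) calls 97 differed between both forms, as did 1763 of the 2833 AgNP calls.

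The treatment effect differed between library series for 364 genes under AgNP, 168 under Ag(aq) and 32 between both forms, of which 232, 141 and 21 had opposite signs. Without control replicate 1 these were 288, 169 and 80 genes, and without control replicates 1 and 5 they were 159, 121 and 72. Under Ag(aq) 7 of 9 ATP synthase genes differed, with medians of 0.01 in series 34 and -1.86 in series 38. Of the 17 heat-shock genes tested, 12 differed between series, with opposite signs in all 12. In the joint fit 8 of these were called in each series. A fit of series 34 alone called 29 genes under Ag(aq), 24 of them among the 233, which hold no heat-shock gene. Not all of the 8 can thus have been called there, and groEL was not. The interaction had an adjusted p of 1.17e-04 for dnaK and 1.57e-04 for groEL. Ribosomal protein genes had a median of 0.53 in series 34 and -1.15 in series 38, with 16 of 51 called different. Inside each series, PA3205 of the lowest Ag(aq) library exceeded the highest control 43.5-fold (34) and 31.7-fold (38). The 3 AgNP calls PA3920, PA3444 and ahpF had the same direction in both series.

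**Figure D4:**
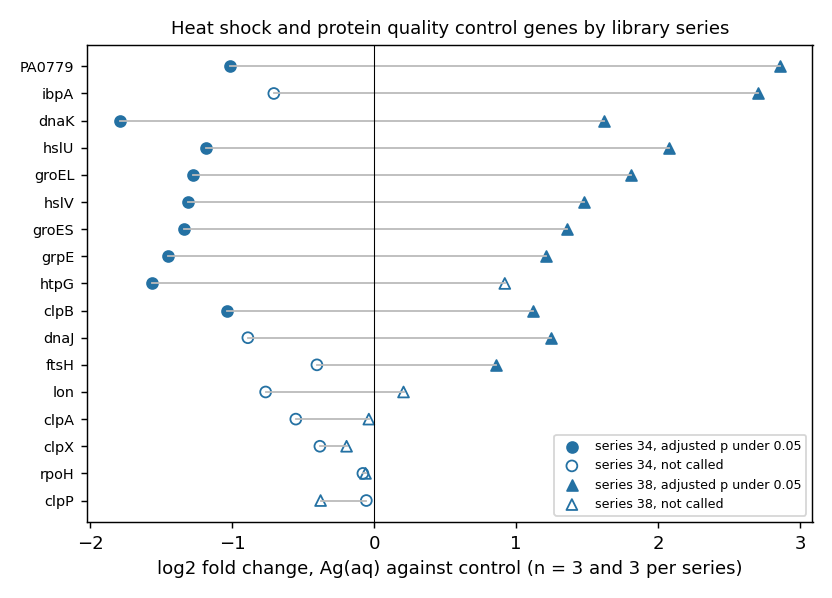
Log2 fold change (horizontal axis) of 17 heat-shock genes, Ag(aq) against control, with circles for library series 34 and triangles for series 38 (n = 3 and 3 in each). Points are joined per gene and filled where the adjusted p of the joint fit was under 0.05. Most genes lie below 0 in series 34 and above 0 in series 38.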

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

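The splits of the libraries and the scaling check of the chaperone pattern were planned before their results were seen, and the other tests were chosen after. In groups of 6 libraries, a library was taken as far from the others by the Dixon gap test, which chance gives in about 1 in 20 groups. Of 249 groups 27 (10.8%) had one, 11 of them in control replicate 1 and 4 in control replicate 5. Differences between library series were taken from the interaction test.

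The wide AgNP response (2833 genes) could come in part from uniform background reads, since the read floor was 16.5% in AgNP and 5.15% in the controls. After floor subtraction 88.15% of the rises outside the 1182 genes of lowest read density and 84.32% of the falls were still called. Of the rises among those 1182 genes 46.43% were still called. Their median log2 fold change was 1.16 (SD across genes 0.37) before and 1.26 (SD 0.70) after. That median cannot decide on background, since subtraction also lowers their control counts, the denominator of the ratio. Their read density increased by a median of 27.6 CPM per kb (quartiles 21.9 to 34.7), against 59.3 (40.5 to 136.8) for the other rises. The origin of these rises cannot be told apart. A first version, with genes filtered anew, kept 92.3%, 68.6% and 34.6% of these 3 sets, and the test was revised after that was seen, so background is argued against by both versions for the rises outside that set, but only by the revised one for the falls. With total counts 75.86% of all calls were kept, all 1411 rises but 51.9% of the falls, so scaling stays open for the falls, as does a response to the particles.

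Regrouping the libraries argued against chance for each comparison, if the 12 libraries are taken as exchangeable. The splits were not kept within library series. AgNP replicates of a series differed by little more than counting error, so they may not count as separate units. In that case the splits overstate the evidence against chance. For AgNP against control 1 of 100 splits, the real one, gave 2833 genes, and the highest other gave 976. For Ag(aq) against control 2 of 100 splits gave at least 233, and the highest other gave 373 from a split that parted the library series 5 to 1, so a series structure stays open. Fitted alone, series 34 and 38 gave 29 and 754 Ag(aq) genes, but 204 and 270 in the joint fit. For AgNP against Ag(aq) 1 of 100 splits gave 2017, and the highest other 806.

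Under Ag(aq), 12 of 17 heat-shock genes differed between library series with estimates of opposite sign, dnaK by 3.41 and groEL by 3.09 more in series 38 than in 34. In the joint fit 8 of them were called in each series, but not all of the 8 in series 34 fitted alone, where groEL was not called. Swapped control and Ag(aq) labels are unlikely, since PA3205 was at least 31.65-fold higher in every Ag(aq) library than in every control of its series. That gene was picked after the results, as one called in the same direction in both series. The controls alone do not account for it, since Ag(aq) itself was higher in series 38 by a median of 1.361 (controls -0.81), although they contribute a part. Scaling is unlikely as well, since the median interaction was 2.49 and with total counts 2.835. An unstated difference between the series, such as batch or growth state, remains open, and no biological explanation was tested since the design names none.

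In control replicate 5 the copper resistance genes pcoA (3398 CPM, 980 reads), pcoB (936 CPM) and PA2807 (1820 CPM) were near their AgNP levels, at 127%, 86.6% and 84.3% of the rise under AgNP. Reads carried over from AgNP libraries are an unlikely cause, since PA3920 was raised by 1.862% of its rise under AgNP. A mislabelled AgNP library is unlikely too, since PA3920, PA3287 and ahpF reached at most 0.08526 of the lowest AgNP library. High PA2807 was not confined to that culture. It had 177 and 249 CPM in control replicates 4 and 6, of the same library series. Control replicates 1, 2 and 3, of the other series, had 13.7, 12.3 and 22.7 CPM. For pcoA, the highest of the other controls had 428 CPM, against their median of 45.2. A difference between the library series thus stays open for PA2807. A selective change of the copper regulon in control replicate 5 also remains open, and no biological explanation was tested since the design names none.

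The effect differed between series for 364 genes under AgNP, 168 under Ag(aq) and 32 between both forms. Under AgNP the difference (series 38 minus 34, log2) was 1.20 for katB, 1.905 for dnaK and 1.495 for groEL. Under Ag(aq) it was -2.579 for PA3206, 4.03 for PA2506, 1.905 for dsbG, 2.78 for exaC, 1.95 for oprH, 1.79 for pstS, 3.409 for dnaK and 3.091 for groEL.

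Control replicate 1 stood apart with 2.78% tmRNA and 2.08% ncRNA reads and with CPM of 6374 for pilA, 6328 for PA5348, 580.3 for cheZ, 155 for cheY, 662.5 for exaB, 1270 for exaC, 7941 for oprD, 109.7 for PA2527 and 498 for flgE. Control replicate 5 had 1.59% rRNA, 457.7 CPM of PA3920, 52.0 of ptrA and 1820 of PA2807. Control replicate 2 had 987 CPM of oprH and control replicate 6 had 219 of PA0646. Among AgNP libraries, replicate 2 had 237 CPM of aqpZ, replicate 3 had 1.14% rRNA and 26.6 CPM of PA0615, replicate 4 had 0.2097% ncRNA and replicate 5 had 2806 CPM of ahpF. Among Ag(aq) libraries, replicate 1 had 2279 CPM of pilA, 28.3 of PA0046 and 87.2 of phzE1, and replicate 3 had 1353 of metE and 3.10 of arsR.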

How the results depend on the processing

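The tests with total counts only, with the read floor subtracted, with AgNP libraries summed per series and without control replicates 1 and 5 were chosen after the data were seen. Genes named by rule and called (91 gene and comparison pairs) kept their sign in every setting that tested them. Of these pairs, 58 stayed called in every setting that tested them. A setting whose count filter removed a gene gave no value for it. Genes named as examples were not followed. Over all settings 3047 of 3248 gene values kept direction and call, 154 lost the call, 19 gained one and 28 changed sign. List medians were followed for the 30 pairs of list and comparison that passed or moved one way, a limit set after near-zero medians of mixed lists were seen to change sign, and of 921 values 888 kept direction and call, 30 lost it, 3 gained it and none changed sign. Left out of that were mixed lists whose AgNP medians changed sign with total counts, among them TCA cycle (-0.24 to 0.19), flagellum (-0.37 to 0.07), type VI secretion (-0.40 to 0.02) and pyocins (-0.40 to 0.03). The zinc and cadmium list under AgNP lost its call in 8 settings and in 9 of the 18 fits without 1 library, sulfate assimilation without the series term, within each series and, against control, with total counts, copper export within series 38, and RND efflux under Ag(aq) within each series, with total counts and with summed AgNP libraries. Depth limits the weakly expressed genes most. DESeq2 kept 2784, 230 and 2000 of the 2833, 233 and 2017 calls, and RLE size factors 2777, 225 and 2003.

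With at least 50 counts in 6 libraries (1529 genes tested) 858, 143 and 854 genes changed for AgNP, Ag(aq) and between both forms, the overlap was 100, r was 0.399 and 460, 245 and 63 genes differed between series, against 364, 168 and 32. Without the series term 141 Ag(aq) genes and an overlap of 95 remained, and with only the 12 libraries compared 114. Series 34 alone gave 1205, 29 and 678 genes, an overlap of 20 and 3 lists under AgNP, and series 38 alone, with as many libraries, gave 2937, 754 and 1880 genes, an overlap of 615, r = 0.680 and 3 lists under AgNP. DESeq2 called 399 genes under Ag(aq). Total counts left 3 lists under AgNP. Floor subtraction left 147 Ag(aq) genes and 3 lists, and summing AgNP libraries 1751, 111 and 692 genes. Without control replicates 1 and 5, 159 (AgNP) and 72 (between forms) genes differed between series. No count filter gave 2 lists under Ag(aq). The preset correlation gave 22, 17 and 12 lists and fry 25, 8 and 18. Controls split between the contrasts gave an overlap of 74.28 and r = 0.389. The cause of these shifts was not tested.

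Same-numbered replicates were not shown to be pairs: their deviations correlated between -0.436 and 0.212 over 18 pairs, 4 above 0.1. In 7 of these 18 the same number was the best match. With a replicate block 2686, 145 and 1810 genes were called and the overlap was 96.

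Sign changes concerned genes not called over all 18 libraries, although recA was called with at least 50 counts (adjusted p = 0.0401 and 0.0132) and dnaK in series 38 (3.98e-06). For recA (PA3617) they were 0.36 (at least 50 counts), 0.20 (total counts) and 0.24 (floor) under AgNP, 0.0460 (total counts) under Ag(aq), and 0.45 (at least 50 counts), 0.24 (series 38), 0.16 (total counts), 0.25 (floor) and 0.0231 (summed AgNP) between forms. Under Ag(aq) dnaK (PA4761) changed to 0.12 (no series term), 1.61 (series 38) and 0.00341 (total counts), groEL (PA4385) to -1.32 (series 34), ahpF (PA0140) to -0.0927 (series 38) and -0.0146 (without controls 1 and 5), and algU (PA0762) to -0.15 and -0.0772 in the same settings. The cause was not tested.

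Leaving out 1 library gave 2482 to 2959, 143 to 260 and 1620 to 2310 changed genes, 4 to 5, 1 to 3 and 4 to 5 lists, and 1381 to 1782, 97 to 176 and 764 to 1150 genes changed at least 2-fold. The lowest Ag(aq) counts were 143 without Ag(aq) replicate 4, 150 without Ag(aq) replicate 5 and 150 without control replicate 4. Without control replicate 1 the series differences were 288, 169 and 80. In these fits dnaK ran from -0.45 to 0.26, ahpF from -0.0281 to 0.17 and algU from -0.0393 to 0.19 under Ag(aq), and recA from -0.19 to 0.0524 between forms. With total counts the called rises were 73.2%, 79.9% and 59.1% of calls, against 49.8%, 45.1% and 45.8%. For Ag(aq) they were 57.9% with the 12 libraries compared, 30.1% in series 38, 61.2% after floor subtraction and 56.2% without rRNA and tRNA, and for AgNP 60.8% with summed libraries.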

Other observations

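The gene groups described here were chosen after their values were seen, as were all tests on them. Both forms of silver raised most genes of the cluster PA2475 to PA2481, which includes the disulfide isomerase gene dsbG. Under Ag(aq) 6 of 7 rose and PA2481 fell by 0.86, with a median of 2.37, and 5 differed between library series. Under AgNP 5 rose, with dsbG at 1.88 ± 0.35, and 1 fell, PA2481 (-2.14). The pump operon PA2525 to PA2528 rose in all 4 genes under Ag(aq) (1.58 to 1.96). Under AgNP edgeR called 0 of its 4 genes (0 at an unadjusted p under 0.05, 0 by DESeq2), and all 4 were lower in AgNP than in Ag(aq) (-1.77 to -1.57). PA3205 also rose under AgNP, by 3.23 ± 0.29, with PA3206 (2.36 ± 0.41) and PA3207 (1.91 ± 0.50), while the neighbouring regulator gene PA3204 was not called by edgeR under either form, although DESeq2 called it under AgNP (-0.48 ± 0.21 and 0.29 ± 0.20).

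In a group of 7 methionine and S-adenosylmethionine genes, 6 fell under AgNP while metY rose (1.38 ± 0.21), and under Ag(aq) metE, metK and PA0547 fell. S-adenosylmethionine synthase metK changed by -2.19 ± 0.24 under AgNP and -1.63 ± 0.24 under Ag(aq), and the regulator gene PA0547 by -2.53 ± 0.32 and -1.67 ± 0.31. Both transhydrogenase genes fell under both forms, pntB by 1.19 and 1.44. Genes for ethanol oxidation through a quinone cofactor fell under Ag(aq) in 8 of 13 (median -1.47) and under AgNP in 6 of 13 (median -0.94). Those falls came mainly from series 34, as in series 38 under AgNP exaB was at 0.86 and exaC at 0.34, and 4 members differed between series. Controls varied widely (exaC 361 ± 455 CPM, SD, n = 6), with exaB and exaC highest in control replicate 1. The 3 arsenic genes rose under AgNP, arsR by 2.19 ± 0.30, arsB by 2.15 ± 0.26 and arsC by 4.01 ± 0.45. Under Ag(aq) arsB (0.16 ± 0.31) and arsC (0.57 ± 0.68) were not called. The cluster PA3515 to PA3518 beside the copper export genes rose in 4 of 4 genes under AgNP (2.50 to 5.43) and in 2 of 4 under Ag(aq), PA3516 (1.39 ± 0.30) and PA3518 (1.83 ± 0.35). The copper-chaperone gene PA3574a rose by 4.14 ± 0.21 under AgNP, and PA3575 rose under both forms, by 2.10 ± 0.34 and 2.97 ± 0.32.

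Library measures outside the comparisons were as follows. TMM factors averaged 0.871 in the controls, 1.15 in AgNP and 1.02 in Ag(aq), and between 5354 and 5623 features had a read. The 20 most abundant genes took 14.2% of counts on average. The chi-square per degree of freedom between replicates of a series was 1.05 to 1.50 in AgNP, 2.26 to 15.0 in the controls and 1.86 to 15.0 in Ag(aq).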
